A study of Arabidopsis thaliana with 12 samples.

How the data were processed

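RNA was sequenced from 5-day-old Arabidopsis thaliana seedlings of wild type (WT) and of a line labelled rve5-2, an allele name of the gene RVE5 (REVEILLE 5). Both genotypes had grown at 22 °C in long days and were then kept for 12 h at 22 °C or at 29 °C, and all were collected at zeitgeber time 12 h, that is 12 h after lights on. The temperature of each library was taken from its own label, since the treatment text that all samples share names 29 °C throughout. The 4 combinations of genotype and temperature have 3 libraries each, 12 in all. Per the labels, RNA was taken with Trizol and libraries were made with an Illumina TruSeq RNA kit, which does not mark the strand. The labels do not say whether the replicates were separate cultures, so the p-values measure the spread between these libraries.

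The deposited table has a column headed as counts for each library, and its values are whole numbers. The headers do not say whether these are raw, and they were analysed as raw counts. The table also has an FPKM column for each library (fragments per kilobase of transcript, scaled to library size), which the authors computed and in which genes with a count of 0 hold a fixed small value. The submitters name cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d and edgeR, and the build TAIR10. Which of these made each column and how reads were assigned to genes are not stated. Low counts pile up at about every 4th whole number, at a spacing of 3.73, so 1 fragment seems to have added about 4 to a count. The count totals of 65.9 to 89.1 M per library would then stand for about 17.7 to 23.9 M fragments (M, 1e6). Intervals and floors cover counting error only, and a floor is 3 fragments over a group, each taken as 3.73 counts. A fold of the floor sets the mean of the higher group against the floor of the group without counts. It takes that mean as measured, without its own counting error.

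The table lists 32399 genes, of which 31912 loci were found in the reference annotation, and 9854 have the same start and end there. Positions are those of the table. Of these genes, 7821 had a count of 0 in every library. A gene symbol stands in the table for 2818 genes. The 338 loci of the gene lists were looked up by locus.

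Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its minimum count of 10, which left 21870, libraries were scaled by TMM, and a quasi-likelihood model with 1 mean per group was fitted to all 12 libraries together. The 5 contrasts were 29 °C against 22 °C in each genotype, the libraries labelled rve5-2 against WT at each temperature, and the interaction, which is the warm response of the libraries labelled rve5-2 minus that of WT. p-values were adjusted by Benjamini and Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. Expression is given as CPM (counts per 1e6 counts after TMM scaling) with the SD over 3 libraries. The SE of a log2 fold change is its size divided by the root of the quasi-likelihood F, which is an approximation.

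The comparisons, tests, lists and most alternatives were fixed before the data were examined. The 23 lists cover morning clock genes, evening clock genes, PIF factors and shade-type regulators, auxin biosynthesis, auxin response, SAUR growth genes, cell wall loosening, gibberellin, brassinosteroids, heat shock, cold response, abscisic acid response, light-harvesting and Rubisco small-subunit genes, the flavonoid pathway, flowering, salicylic acid defence, jasmonate response, sugar starvation, cell division, root tissue markers, seed storage markers, stomatal lineage markers and reference genes. Each was tested with camera in limma 3.58.1, with a preset correlation between genes of 0.01 and with an estimated one, and with fry. Camera sets the members against all other genes, while fry asks only whether the members changed. The adjusted p of a list is that of camera unless fry is named. List p-values were adjusted over the 23 lists of a comparison. Calls of members are given over all genes tested and adjusted over the list alone. Genes were named by a fixed rule: RVE5, CCA1, LHY, PIF4 and YUC8 always, then the 6 largest rises and 6 largest falls among called genes with a symbol in the table whose libraries do not overlap between groups, then up to 3 members of each list with the smallest adjusted p. Other names are said to have been chosen after their values were seen.

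For pairs of comparisons that share no library, the overlap of calls was set against the number expected of independent lists, and the log2 fold changes were correlated across genes. The error of that correlation is a jackknife over libraries. Genes are not independent replicates, so no p-value is given for it. The 2 correlations are the only ones computed between comparisons.

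The alternatives tried were pseudocounts of 0.1 and 0.5 in limma on log2 FPKM, no filter on low counts, a mean FPKM of at least 5, median-of-ratios scaling, quantile normalization, limma without a variance trend and with array weights, DESeq2 1.42.0, the compared groups alone in the fit, the replicate number as a block, a 2-fold minimum, an estimated correlation in the list tests, and each library left out in turn. Added after the data were seen were limma on log2(FPKM + 1), counts divided by 4 and rounded, and the mean log2 CPM of the 14 root markers as a covariate, here called the root score. The list tests without replicate 1 of WT at 29 °C were also added then. Term enrichment used the gene ontology terms given in the deposited table and a hypergeometric test. Terms with 10 to 500 genes among the 18706 tested genes that carry a term were kept. The share of a gene's 50-base stretches that also occur elsewhere in the reference genome, on either strand, was counted as a measure of repeated sequence. A repeat within the gene itself counts too.

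The edgeR fit was tested on simulated data. With 200 genes changed, it recovered 43 to 72% of 2-fold changes and 76 to 91% of 4-fold changes, the lowest of each in the interaction, and 4.03 to 5.95% of its calls were unchanged genes. The changed genes were drawn only from genes with counts well above the filter's minimum, and genes varied independently of each other. Recovery at lower counts, or with variation shared between genes, was not measured. The figures were drawn with Python 3.11.15 and matplotlib 3.10.9.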

Results

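Transcript levels were measured by RNA sequencing in 12 libraries of Arabidopsis seedlings, 3 in each of 4 groups: WT at 22 °C, WT at 29 °C, and the libraries labelled rve5-2 at 22 °C and at 29 °C. By its title the study asks how REVEILLE 5 and the clock factor CCA1 bear on hypocotyl growth in warmth. Total counts were 74.2, 74.8 and 82.3 M in WT at 22 °C and 89.1, 76.8 and 83 M in WT at 29 °C. They were 73.7, 70.1 and 87.1 M in the libraries labelled rve5-2 at 22 °C and 83.4, 65.9 and 76.3 M in those at 29 °C. The 10 most abundant genes took 8.24 to 11.2% of a library.

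RVE5 (AT4G01280, chromosome 4, 535211 to 537322, a Myb-like transcription factor related to CCA1 and LHY) was far higher, not lower, in the libraries labelled rve5-2. Its mean level at 22 °C was 14.9 ± 0.757 CPM in WT and 1011 ± 68.1 CPM in the libraries labelled rve5-2 (SD, n = 3 each), a 67.7-fold difference. At 29 °C the means were 15.1 ± 1.66 CPM and 1329 ± 85.6 CPM, an 88-fold difference. The log2 fold changes were 6.08 (SE 0.11, adjusted p = 1.05e-11) at 22 °C and 6.46 (SE 0.11, adjusted p = 6.16e-12) at 29 °C. All 6 libraries so labelled lay above all 6 WT libraries. WT showed no warm response of RVE5 past the test (log2 fold change 0.02, SE 0.093, adjusted p = 0.924). In the libraries labelled rve5-2 it rose at 29 °C by 0.40 on the log2 scale (SE 0.09, adjusted p = 0.00787). This call ended with quantile normalization (0.20, adjusted p = 0.0726) and with the root score as a covariate (0.15, adjusted p = 0.566). Every genotype comparison given here is therefore one between libraries with low and with high RVE5 counts, and the direction that the allele name might imply is not assumed. The next gene on the chromosome, AT4G01290 (537990 to 543869, chosen after its values were seen), fell by 0.75 on the log2 scale at 22 °C (SE 0.061, adjusted p = 0.000128). At 29 °C it fell by 1.18 (SE 0.061, adjusted p = 9.89e-07). Genes on other chromosomes also differed strongly, among them EXO70H4 and AT5G35935, chosen after their values were seen. Their log2 fold changes at 22 °C were 8.47 and -7.21. Differences between the genotypes can therefore not be assigned to RVE5 alone.

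**Figure D1:**
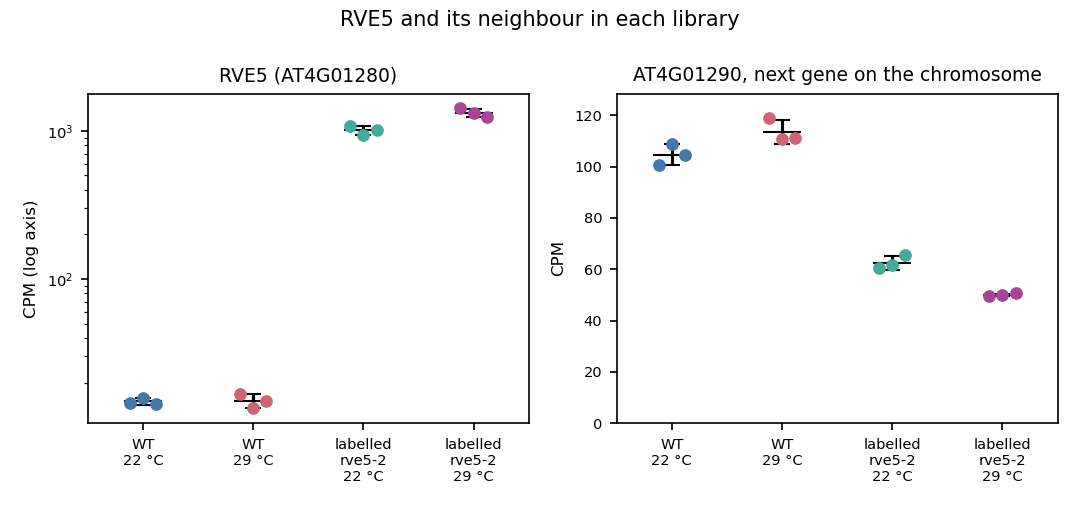
CPM of RVE5 (left, log axis) and of the next gene AT4G01290 (right, linear axis from 0) in each of the 12 libraries, with the mean and SD of each group of 3. RVE5 lies between 13.4 and 16.7 CPM in the 6 WT libraries and between 939 and 1417 CPM in the 6 libraries labelled rve5-2, and AT4G01290 is lower in the latter.

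WT at 29 °C was compared with WT at 22 °C, which gives the wild-type response to 12 h of warmth. Heat shock and clock genes were higher at 29 °C, with the preset correlation and with an estimated one. PIF and shade-type, SAUR and light-harvesting genes were higher, and cold-responsive, flavonoid and root marker genes lower, with the preset correlation but not with an estimated one. In fry these lists passed, at adjusted p from 0.00488 to 0.0212. Auxin biosynthesis (lower) and cell division genes (higher) did likewise, with fry adjusted p of 0.0164 and 0.0477. The root markers fell together with the rise in temperature, from a mean log2 CPM of 2.60 to 0.36, so the response to warmth and the share or state of root are not separated here. PIF4 (AT2G43010, chromosome 2, 17886427 to 17889050), a transcription factor that promotes hypocotyl growth in warmth, rose from 21.1 ± 2.93 to 47 ± 8.15 CPM (SD, n = 3 each; log2 fold change 1.15, SE 0.14, adjusted p = 0.00051). The auxin biosynthesis gene YUC8 (AT4G28720) stood at 2.46 ± 1.05 and 2.24 ± 0.296 CPM (adjusted p = 0.825). The morning clock factors CCA1 (AT2G46830) and LHY (AT1G01060) peak at dawn and were low at this hour. Levels were 0.416 ± 0.315 and 0.736 ± 0.295 CPM for CCA1 and 0.936 ± 0.464 and 0.717 ± 0.0365 CPM for LHY, with adjusted p of 0.318 and 0.67. In edgeR 1767 genes rose and 1620 fell among the 21870 tested, 181 and 518 of them by at least 2-fold. Falls outnumbered rises in limma on log2(FPKM + 1), with 2003 against 1499.

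Among heat shock genes in WT 14 of 26 tested members rose and none fell, and 19 rose adjusted over the list alone. The list was higher in camera (adjusted p = 7.83e-30, and adjusted p = 0.00579 with an estimated correlation). The chaperone gene HSP90.1 (AT5G52640) rose from 17.9 ± 1.79 to 114 ± 9.72 CPM (log2 fold change 2.68, SE 0.14, adjusted p = 1.33e-06). The immunophilin gene ROF2 (AT5G48570) rose by 2.29 (SE 0.12) and the small heat shock gene HSP23.5 (AT5G51440) by 2.80 (SE 0.19) on the log2 scale. Among morning clock genes 5 of 15 rose, 7 adjusted over the list alone, and none fell (adjusted p = 7.47e-12, and adjusted p = 0.00516 with an estimated correlation). LNK1 (AT5G64170), a clock coactivator, rose from 6.24 ± 1.25 to 28.1 ± 0.625 CPM (log2 fold change 2.17, SE 0.12, adjusted p = 1.33e-06). The pseudo-response regulator PRR7 (AT5G02810) rose by 2.06 (SE 0.12) on the log2 scale to 72.7 ± 8.03 CPM, and RVE7 (AT1G18330) by 1.17. Of 13 evening clock genes 5 rose and 1 fell, also adjusted over the list alone (list higher, adjusted p = 1.5e-05, and adjusted p = 0.0295 with an estimated correlation, which was 0.0503 without replicate 1 of WT at 29 °C). GI (AT1G22770) rose by 1.44 (SE 0.11), LUX (AT3G46640) by 0.95 (SE 0.075) and TOC1 (AT5G61380) by 0.39 (SE 0.074) on the log2 scale. The member that fell was ELF4 (AT2G40080), by a log2 change of -0.41 (SE 0.11, adjusted p = 0.0255, named after its values were seen), and without replicate 1 of WT at 29 °C no member was called lower.

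**Figure D2:**
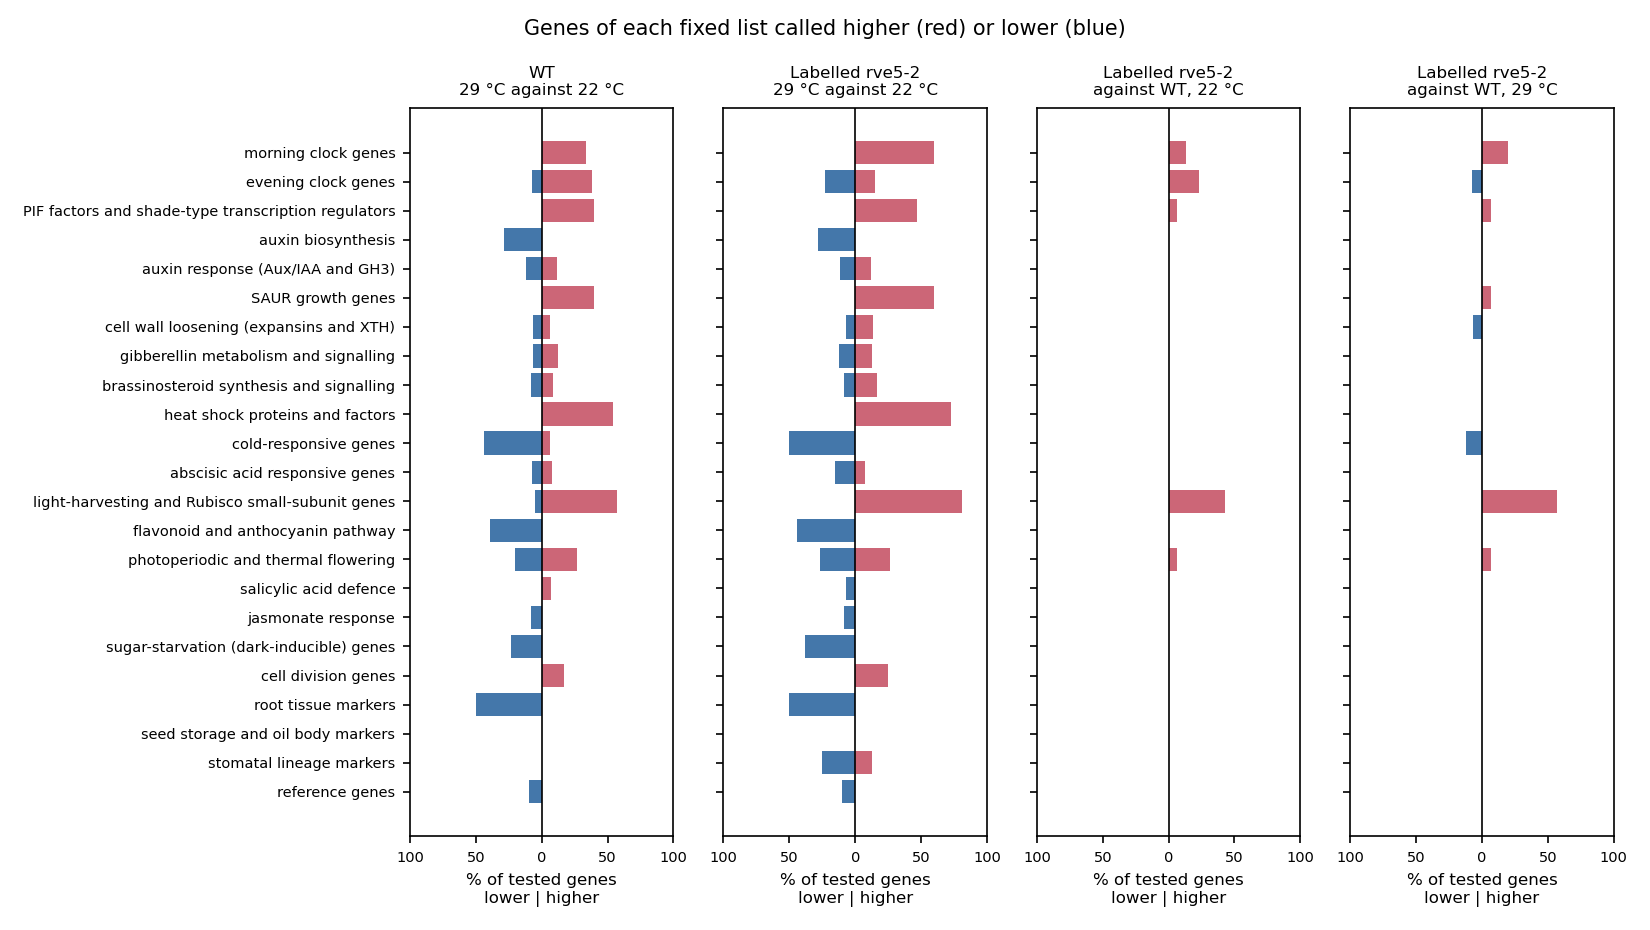
Share of tested members of each of the 23 lists called higher (red, right of 0) or lower (blue, left of 0) at an adjusted p under 0.05 in edgeR, as a percentage, in the 4 comparisons between groups. Called heat shock genes rise with warmth in both genotypes. Of the root markers 7 of 14 are called lower in each, a list result that does not hold with an estimated correlation (adjusted p = 0.225 and 0.241). In fry the root marker list passes in each (adjusted p = 0.0102 and 0.00697). Of the light-harvesting genes 9 and 12 of 21 are called higher in the libraries labelled rve5-2 at 22 °C and 29 °C.

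Of 15 PIF and shade-type regulators 6 rose and none fell, over all genes and adjusted over the list alone (list higher, adjusted p = 0.000147, but adjusted p = 0.225 with an estimated correlation). Without replicate 1 of WT at 29 °C 4 rose. PIF5 (AT3G59060) rose by 1.35 (SE 0.18) and the shade-responsive factor ATHB2 (AT4G16780) by 0.99 (SE 0.17) on the log2 scale. Of 15 SAUR genes, which are auxin-inducible and promote cell expansion, 6 rose and none fell, 8 adjusted over the list alone (adjusted p = 0.000126, but adjusted p = 0.255 with an estimated correlation). Without replicate 1 of WT at 29 °C 2 rose. SAUR22 (AT5G18050) rose from 1 ± 0.404 to 3.36 ± 0.34 CPM (log2 fold change 1.74, SE 0.30, adjusted p = 0.00337). Among 21 light-harvesting and Rubisco small-subunit genes 12 rose and 1 fell, 15 and 1 adjusted over the list alone (adjusted p = 1.86e-14, but adjusted p = 0.225 with an estimated correlation). LHCB2.2 (AT2G05070), an antenna protein gene of photosystem II, rose from 35.7 ± 2.49 to 154 ± 30.5 CPM (2.11, SE 0.18). LHCB2.1 (AT2G05100) rose by 1.93 and LHCB4.2 (AT3G08940) by 1.32 on the log2 scale. The member that fell was LHCB1.2 (AT1G29910), by a log2 change of -0.45 (named after its values were seen). LHCB2.1 and LHCB2.2 have 21.4% and 25.9% of their 50-base stretches also elsewhere in the reference genome, so their counts may not be separate. Of 12 cell division genes 2 rose, CDKB2;1 (AT1G76540) by 0.51 and CDC20.1 (AT4G33270) by 0.40, and 4 adjusted over the list alone (adjusted p = 0.0279, but adjusted p = 0.556 with an estimated correlation).

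Of 16 cold-responsive genes 7 fell and 1 rose, 9 and 2 adjusted over the list alone (list lower, adjusted p = 4.09e-05, but adjusted p = 0.245 with an estimated correlation). The cold- and drought-responsive RD29A (AT5G52310) fell by 2.03 (SE 0.17) and KIN1 (AT5G15960) fell by 4.45 (SE 0.61) on the log2 scale. The member that rose was COR27 (AT5G42900), a cold-induced regulator that also acts in the clock (0.55, SE 0.091). Of 18 flavonoid genes 7 fell and none rose, also adjusted over the list alone (adjusted p = 2.84e-05, but adjusted p = 0.299 with an estimated correlation). Chalcone isomerase CHI (AT3G55120) fell from 92.3 ± 0.327 to 33.9 ± 9.18 CPM (log2 fold change -1.45, SE 0.16, adjusted p = 0.000313). The hydroxylase genes F3PH (AT5G07990) and F3H (AT3G51240) fell by 1.80 and 1.54 on the log2 scale, respectively. Of 7 auxin biosynthesis genes 2 fell, also adjusted over the list alone (adjusted p = 0.0279, but adjusted p = 0.299 with an estimated correlation). They were CYP79B2 (AT4G39950), by a log2 change of -0.93, and CYP79B3 (AT2G22330), by one of -0.76. Both encode enzymes that make indole-3-acetaldoxime, from which indole glucosinolates also come. Of 14 root markers 7 fell and none rose, 9 adjusted over the list alone (adjusted p = 6.46e-08, but adjusted p = 0.225 with an estimated correlation). The root hair genes LRX1 (AT1G12040), PRP3 (AT3G62680) and XTH14 (AT4G25820) fell by 2.79 (SE 0.39), fell by 3.36 (SE 0.57) and fell by 2.82 (SE 0.51) on the log2 scale.

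The other 12 lists did not pass in WT, with camera adjusted p from 0.22 to 0.896. Rises and falls were 2 and 2 of 17 auxin response genes, 1 and 1 of 15 cell wall loosening genes, 2 and 1 of 16 gibberellin genes, 1 and 1 of 12 brassinosteroid genes, and 1 and 1 of 13 abscisic acid responsive genes. They were 4 and 3 of 15 flowering genes, 1 and 0 of 14 salicylic acid genes, 0 and 1 of 12 jasmonate genes and 0 and 3 of 13 sugar-starvation genes. No seed storage marker of 3 and no stomatal lineage marker of 8 was called, and of 10 reference genes GAPC1 (AT3G04120) fell by 0.39 on the log2 scale. Adjusted over the list alone these counts were 2 and 2 for gibberellin, 1 and 2 for abscisic acid and 1 and 4 for sugar-starvation genes, and as above for the others. By name, the flowering repressor SVP (AT2G22540) rose by 0.64, CDF1 (AT5G62430) by 1.03 and CDF3 (AT3G47500) by 0.81. JAZ1 (AT1G19180) fell by 1.43, GA3OX2 (AT1G80340) fell by 1.39 and TPS10 (AT1G60140) fell by 1.09 on the log2 scale. IAA7 (AT3G23050) rose by 0.41, XTH16 (AT3G23730) by 0.81 and CPD (AT5G05690) by 0.41.

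Among the largest changes of genes with a symbol, HSP17.4 (AT3G46230) rose from 0.171 ± 0.061 to 5.16 ± 1.16 CPM (log2 fold change 4.91, SE 0.63, adjusted p = 0.000715). The carotenoid hydroxylase gene BETA-OHASE_2 (AT5G52570) rose from 0.135 ± 0.102 to 1.22 ± 0.131 CPM. HSP17.6II (AT5G12020) reached 0.799 ± 0.102 CPM and HSP23.6 (AT4G25200) 0.613 ± 0.308 CPM, with 5 and 4 counts in all at 22 °C. BGLU28 (AT2G44460) and CPK17 (AT5G12180) had no counts at 22 °C, and their means at 29 °C were 16.9-fold and 4.17-fold the floor. DIN6 (AT3G47340), an asparagine synthetase gene induced by darkness, had none at 29 °C, and its mean at 22 °C was 9.91-fold the floor. The root hair gene RHS19 (AT5G67400) fell by 2.81 and RHS18 (AT5G22410) fell by 3.84. GPAT7 (AT5G06090) fell by 2.46, BGLU45 (AT1G61810) fell by 2.45 and GSTU22 (AT1G78340) fell by 2.24 on the log2 scale. The calls of BGLU28 and CPK17 ended without any library but replicate 3 at 29 °C, at adjusted p of up to 0.108 and 0.0954. Those of HSP23.6 (up to 0.12) and GPAT7 (0.0632) ended without replicate 2 or 3 at 22 °C or replicate 2 at 29 °C, and HSP23.6 also without replicate 1 at 29 °C. Those of RHS18 (0.0502), GAPC1 (0.0562) and GSTU22 (0.053) ended without replicate 3 at 22 °C, BGLU45 (0.0518) without replicate 1 there, and GSTU22 and BGLU45 also without replicate 2 at 29 °C. Of the 63 named and called genes 43 were called without each of the 6 libraries in turn, and 15 with the root score in the fit.

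The root score, the mean log2 CPM of the 14 root markers, was 2.60 ± 0.40 in WT at 22 °C and 0.36 ± 1.36 in WT at 29 °C (SD, n = 3 each). It was 2.70 ± 0.14 and 0.26 ± 0.71 in the libraries labelled rve5-2, so the score moved together with temperature. Replicate 1 of WT at 29 °C had the lowest score, -1.21, and the lowest level of its group in 14 of 14 markers. With the root score in the fit, an alternative added after seeing the data, 175 genes were called in WT, 154 of them as before, and 46 of the 3387 genes turned direction. The SE of these 3387 genes became larger by a median factor of 1.48 and their log2 fold changes became smaller by a median factor of 0.691. HSP90.1 (2.91, SE 0.18) and PRR7 (1.81, SE 0.15) stayed called, and PIF4 did not (0.90, SE 0.20, adjusted p = 0.0562). The count was 2147, 2249 and 1747 without replicates 1, 2 and 3 of WT at 22 °C, and 1687 with only the WT libraries in the fit.

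**Figure D3:**
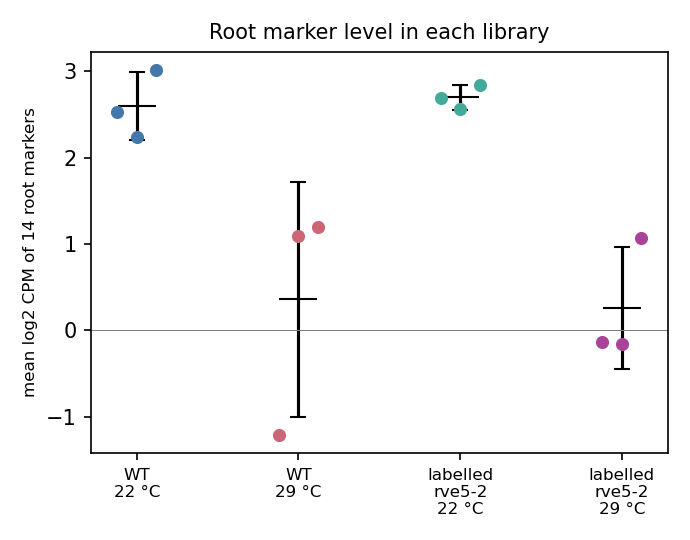
Mean log2 CPM of the 14 root markers in each of the 12 libraries, with the mean and SD of each group of 3. The score is lower at 29 °C in both genotypes, and replicate 1 of WT at 29 °C is lowest at -1.21.

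The libraries labelled rve5-2 at 29 °C were compared with those at 22 °C, which asks for the same warm response where RVE5 was high. Heat shock and morning clock genes were higher at 29 °C as lists, with the preset correlation and with an estimated one, and the evening clock genes did not pass. PIF and shade-type, SAUR and light-harvesting genes were higher, and cold-responsive, flavonoid, sugar-starvation and root marker genes lower, with the preset correlation but not with an estimated one. In fry these lists passed, at adjusted p from 0.000535 to 0.0217. PIF4 rose from 41.6 ± 5.71 to 81.6 ± 5.81 CPM (SD, n = 3 each; log2 fold change 0.97, SE 0.14, adjusted p = 0.000575), a call that ended with the root score in the fit (0.71, SE 0.20, adjusted p = 0.0884). YUC8 stood at 2.21 ± 0.947 and 4.42 ± 1.05 CPM (adjusted p = 0.0545). CCA1 stood at 0.872 ± 0.225 and 2.49 ± 0.711 CPM (adjusted p = 0.0523) and LHY at 1.37 ± 0.249 and 1.17 ± 0.884 CPM (adjusted p = 0.795). In edgeR 2848 genes rose and 2848 fell, 324 and 946 of them by at least 2-fold. The even split was not general: 1951 rose and 3748 fell in limma on log2(FPKM + 1), 2498 and 4914 with array weights, and 3139 and 2786 with quantile normalization. The warm calls of both genotypes shared 1424 genes that rose, against 230 expected of independent lists, and 1254 that fell, against 211, and 2 genes were called in opposite directions. Across 21870 genes the log2 fold changes had a Pearson r of 0.546 (jackknife SE 0.0791) and a Spearman rho of 0.721, and r was 0.28 without a filter on low counts and 0.847 at a mean FPKM of at least 5. With each library left out r was 0.406 to 0.489, always below 0.546, so the jackknife SE is not a sound error.

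Heat shock genes rose in 19 of 26 members, 20 adjusted over the list alone (adjusted p = 1.3e-24, and adjusted p = 0.00847 with an estimated correlation). ROF2 had a log2 fold change of 2.34 (SE 0.13), HSP90.1 of 2.31 (SE 0.14) and the coactivator gene MBF1C (AT3G24500) of 2.25 (SE 0.14). Morning clock genes rose in 9 of 15, 11 adjusted over the list alone (adjusted p = 3.73e-10, and adjusted p = 0.00847 with an estimated correlation). LNK1 rose by 1.77 (SE 0.12), PRR7 by 1.52 (SE 0.12) and RVE7 by 1.33 (SE 0.12). Of 13 evening clock genes 2 rose and 3 fell (adjusted p = 0.592), also adjusted over the list alone. GI rose by 0.77 (SE 0.11; adjusted p = 0.0551 with the root score) and LUX by 0.52 (SE 0.074). ELF4, a partner of LUX in the evening complex, fell from 55 ± 3.42 to 22.2 ± 3.04 CPM (log2 fold change -1.31, SE 0.11, adjusted p = 2.36e-05). SAUR genes rose in 9 of 15, 13 adjusted over the list alone (adjusted p = 2.24e-07, but adjusted p = 0.172 with an estimated correlation). PIF and shade-type regulators rose in 7 of 15, over all genes and adjusted over the list alone (adjusted p = 0.00043, but adjusted p = 0.172 with an estimated correlation). SAUR62 (AT1G29430) rose by 1.13 (SE 0.16), SAUR20 (AT5G18020) by 1.17 (SE 0.17), PIF5 by 1.31 (SE 0.18) and ATHB2 by 1.25 (SE 0.17). Light-harvesting and Rubisco small-subunit genes rose in 17 of 21, over all genes and adjusted over the list alone (adjusted p = 1.76e-19, but adjusted p = 0.17 with an estimated correlation). LHCB2.2 rose by 2.07 (SE 0.18) and LHCB4.2 by 1.51 (SE 0.13).

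Cold-responsive genes fell in 8 of 16, 10 adjusted over the list alone (adjusted p = 1.01e-08, but adjusted p = 0.0939 with an estimated correlation). RD29A fell by 2.64 (SE 0.18), COR15A (AT2G42540) fell by 4.26 (SE 0.67) and COR47 (AT1G20440) fell by 1.29 (SE 0.20) on the log2 scale. Flavonoid genes fell in 8 of 18, also adjusted over the list alone (adjusted p = 5.61e-05, but adjusted p = 0.382 with an estimated correlation). CHI had a log2 change of -1.42 (SE 0.16) and the flavonol synthase gene FLS1 (AT5G08640) one of -1.79 (SE 0.28). Root markers fell in 7 of 14, also adjusted over the list alone (adjusted p = 2.85e-07, but adjusted p = 0.241 with an estimated correlation). LRX1 fell by 4.02 (SE 0.42) and the root hair expansin gene EXPA7 (AT1G12560) fell by 3.27 (SE 0.46). Sugar-starvation genes fell in 5 of 13, 5 lower and 1 higher adjusted over the list alone (adjusted p = 0.0376, but adjusted p = 0.172 with an estimated correlation). TPS10 fell by 1.40 (SE 0.21) and the dormancy-associated gene DRM2 (AT2G33830) fell by 1.63 (SE 0.26). The other 13 lists had camera adjusted p from 0.122 to 0.992. Rises and falls were 0 and 2 of 7 auxin biosynthesis, 2 and 2 of 17 auxin response, 2 and 1 of 15 cell wall, 2 and 2 of 16 gibberellin, 2 and 1 of 12 brassinosteroid, 1 and 2 of 13 abscisic acid, and 4 and 4 of 15 flowering genes. They were 0 and 1 of 14 salicylic acid, 0 and 1 of 12 jasmonate, 3 and 0 of 12 cell division, 1 and 2 of 8 stomatal and 0 and 1 of 10 reference genes, and 0 of 3 seed storage markers. Adjusted over the list alone they were 2 and 3 for auxin biosynthesis, 2 and 3 for auxin response, 4 and 6 for flowering, 4 and 0 for cell division and 2 and 2 for stomatal genes, and as above for the others. Of their named members, CYP79B2 fell by 1.13, the defence gene PR5 (AT1G75040) fell by 2.93, JAZ1 fell by 1.67, ROT3 (AT4G36380) fell by 1.26 and MYB60 (AT1G08810) fell by 0.98. EPFL9 (AT4G12970), a peptide gene that promotes stomata, rose by 0.70, EXPB1 (AT2G20750) by 0.71 and RGL2 (AT3G03450) by 0.89. Replicate 1 of WT at 29 °C enters the shared spread. Without that library, rises and falls over all genes were 1 and 3 for auxin biosynthesis genes. They were 2 and 4 for auxin response and for cell wall genes, and 10 of 14 root markers fell.

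The largest changes with a symbol included HSP17.4, which rose from 0.105 ± 0.101 to 5.61 ± 1.86 CPM, and BETA-OHASE_2, which rose from 0.262 ± 0.166 to 4.7 ± 1.6 CPM. FT (AT1G65480), the florigen gene, stood at 0.429 ± 0.12 CPM at 22 °C, 8.17-fold the floor, and had no counts at 29 °C. RHS14 (AT4G22080), PPa3 (AT2G46860) and RHS2 (AT1G05990) also had none at 29 °C, and their means at 22 °C were 36.3-fold, 22.4-fold and 7.07-fold the floor. The terpene synthase gene TPS14 (AT1G61680) and CPK17 had none at 22 °C, and their means at 29 °C were 6.61-fold and 2.22-fold the floor. HSP23.6 stood at 0.632 ± 0.292 CPM and HSP17.6II at 0.893 ± 0.177 CPM at 29 °C, and GSTU4 (AT2G29460) and CPT (AT2G23410) had 5 and 4 counts in all there. The call of CPK17 ended without any 1 of the 6 libraries (adjusted p of up to 0.0952) and that of TPS14 without any but replicate 3 at 29 °C (0.0779). The calls of HSP23.6 (0.113), HSP17.6II (0.0629) and CPT (0.0998) ended without replicate 1 at 22 °C, HSP23.6 also without replicate 2 there, and HSP17.6II and CPT also without replicate 3 there. At 29 °C, leaving out replicate 1 ended those of HSP23.6, CPT and GSTU4 (0.0597), replicate 2 that of HSP23.6 and replicate 3 that of CPT. With the root score in the fit 511 genes were called, 453 of them as before. Of the 5696 genes 353 turned direction, and 23 of the 72 named and called genes stayed called. The count was 3612 and 3590 without replicates 1 and 2 at 29 °C.

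The libraries labelled rve5-2 were compared with WT at 22 °C, which asks how the line differed from WT without warmth. As lists, the light-harvesting and the morning and evening clock genes were higher where RVE5 was high, though 2 of 15 morning and 3 of 13 evening clock genes were called. All libraries come from a single time of day. A shift in the phase of the clock between genotypes could therefore give such differences at either temperature, and was not tested. In edgeR 30 genes were higher and 12 lower, 17 and 1 of them by at least 2-fold. PIF4 was higher, at 41.6 ± 5.71 against 21.1 ± 2.93 CPM in WT (SD, n = 3 each; log2 fold change 0.98, SE 0.14, adjusted p = 0.0098). This call ended without any 1 of 3 libraries, at an adjusted p of up to 0.0643 (replicate 2 or 3 of WT or replicate 1 of the libraries labelled rve5-2). CCA1 stood at 0.872 ± 0.225 against 0.416 ± 0.315 CPM (adjusted p = 0.814), LHY at 1.37 ± 0.249 against 0.936 ± 0.464 CPM (adjusted p = 0.94) and YUC8 at 2.21 ± 0.947 against 2.46 ± 1.05 CPM (adjusted p = 0.989). EXO70H4 (AT3G09520, chromosome 3, 2923743 to 2925629, an exocyst subunit gene), chosen after its values were seen, stood at 285 ± 5.36 CPM against 0.802 ± 0.093 CPM (log2 fold change 8.47, SE 0.23, adjusted p = 5.95e-10). AT5G35935 (chromosome 5, 14083388 to 14089891), also chosen after its values were seen, stood at 0.131 ± 0.129 CPM against 19.8 ± 2.1 CPM (log2 fold change -7.21, SE 0.60, adjusted p = 0.000128).

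Of 21 light-harvesting and Rubisco small-subunit genes 9 were higher and none lower at 22 °C, 13 and 1 adjusted over the list alone (adjusted p = 7.28e-54, and adjusted p = 0.0158 with an estimated correlation). LHCB2.2 stood at 149 ± 28.6 against 35.7 ± 2.49 CPM (log2 fold change 2.06, SE 0.18, adjusted p = 0.000198) and LHCB1.1 (AT1G29920) at 419 ± 43 against 106 ± 21.2 CPM (1.99, SE 0.22, adjusted p = 0.00103). LHCB2.3 (AT3G27690), LHCB2.1 and LHCB3 (AT5G54270) were higher by 1.92, 1.92 and 1.40 on the log2 scale. LHCB2.3 has 0% and LHCB1.1 20.5% of its 50-base stretches also elsewhere in the reference genome. Of 13 evening clock genes 3 were higher, 7 adjusted over the list alone (adjusted p = 3.59e-17, and adjusted p = 0.00153 with an estimated correlation). Of 15 morning clock genes 2 were higher, 4 adjusted over the list alone (adjusted p = 9.97e-12, and adjusted p = 0.00236 with an estimated correlation). PRR7 was higher by 1.39 (SE 0.12, adjusted p = 0.000128), LNK1 by 1.41 (SE 0.12, adjusted p = 0.000128) and GI by 1.16 (SE 0.11, adjusted p = 0.000236), and all 3 kept their calls without each of the 6 libraries. PRR5 (AT5G24470) and LUX were higher by 0.70 and 0.45. These calls ended without replicate 1 or 3 of WT or replicate 1 or 2 of the libraries labelled rve5-2, and for LUX also without replicate 2 of WT, at adjusted p of up to 0.157 and 0.221. Without replicate 1 of WT at 29 °C, which enters the shared spread, 6 evening clock genes, 12 light-harvesting genes and 3 morning clock genes were called higher and 6 flavonoid genes lower.

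Sugar-starvation genes had no member called but were higher as a list at 22 °C (median log2 fold change 0.25, adjusted p = 0.000108, and adjusted p = 0.0271 with an estimated correlation). PIF and shade-type regulators (1 of 15 higher, 3 adjusted over the list alone, adjusted p = 4.76e-05) and flowering genes (1 of 15, CDF3, 3 adjusted over the list alone, adjusted p = 0.000108) were higher as lists. So were SAUR genes (0 of 15, 1 adjusted over the list alone, adjusted p = 0.00012) and cell wall loosening genes (0 of 15, also adjusted over the list alone, adjusted p = 0.0215). With an estimated correlation the adjusted p of these 4 lists were 0.0949, 0.0814, 0.254 and 0.339. In fry they were 0.0469, 0.0298, 0.11 and 0.296. Flavonoid genes (0 of 18 called, 3 lower adjusted over the list alone, adjusted p = 0.000108) and jasmonate genes (0 of 12, also adjusted over the list alone, adjusted p = 0.0209) were lower as lists, at adjusted p = 0.339 and adjusted p = 0.254 with an estimated correlation. Their fry adjusted p were 0.32 and 0.12. The other 13 lists had adjusted p from 0.0535 to 0.856, and none of their members was called, or 1 abscisic acid gene adjusted over the list alone. CDF3, higher by 0.77, lost its call without each of the 6 libraries, at an adjusted p of up to 0.223. The count of 42 was 27 and 25 without replicates 2 and 3 of WT, 26 without replicate 1 of the libraries labelled rve5-2, and 143 in DESeq2.

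The same comparison at 29 °C asks how the line differed from WT in warmth. As lists, the light-harvesting and morning clock genes were again higher in the libraries labelled rve5-2, though 3 of 15 morning clock genes were called. Of single genes PIF4 was higher and ELF4 lower. In edgeR 70 genes were higher and 32 lower, 31 and 7 of them by at least 2-fold. With array weights in limma the balance turned, with 223 higher and 555 lower. PIF4 stood at 81.6 ± 5.81 against 47 ± 8.15 CPM (SD, n = 3 each; log2 fold change 0.79, SE 0.14, adjusted p = 0.0228). The call ended without 5 of the 6 libraries, all but replicate 1 of WT, at an adjusted p of up to 0.135. CCA1 stood at 2.49 ± 0.711 against 0.736 ± 0.295 CPM (adjusted p = 0.289), LHY at 1.17 ± 0.884 against 0.717 ± 0.0365 CPM (adjusted p = 0.835) and YUC8 at 4.42 ± 1.05 against 2.24 ± 0.296 CPM (adjusted p = 0.408). EXO70H4 was again higher (340 ± 4 against 0.893 ± 0.407 CPM, log2 fold change 8.57) and AT5G35935 lower (log2 fold change -7.09), both chosen after their values were seen. The calls at both temperatures shared 23 higher genes, against 0.096 expected of independent lists, and 9 lower ones, against 0.0176, and none in opposite directions. Across 21870 genes the 2 genotype differences had a Pearson r of 0.0951 (jackknife SE 0.037) and a Spearman rho of 0.133, and r was 0.406 at a mean FPKM of at least 5 and 0.0262 without a filter on low counts. Here too r was lower with each library left out (0.0432 to 0.078), so the SE is not a sound error.

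Light-harvesting and Rubisco small-subunit genes were higher in 12 of 21 at 29 °C and none was lower, 16 and 1 adjusted over the list alone (adjusted p = 5.18e-79, and adjusted p = 0.0067 with an estimated correlation). LHCB1.1 stood at 1277 ± 296 against 190 ± 46.8 CPM (log2 fold change 2.75, SE 0.22, adjusted p = 9.69e-05). LHCB2.3, LHCB2.2, LHCB2.1, LHCB3 and LHB1B1 (AT2G34430) were higher by 2.27, 2.02, 1.96, 1.66 and 1.38 on the log2 scale. Morning clock genes were higher in 3 of 15, and 9 were higher and 1 lower adjusted over the list alone (adjusted p = 9.04e-13, and adjusted p = 0.00441 with an estimated correlation). LNK1 was higher by 1.01 (SE 0.11), LNK2 (AT3G54500) by 1.87 (SE 0.25) and PRR7 by 0.85 (SE 0.11). Of 13 evening clock genes ELF4 was lower, at 22.2 ± 3.04 against 41.5 ± 5.47 CPM (log2 fold change -0.90, SE 0.11, adjusted p = 0.00221). None was higher, and adjusted over the list alone 2 were higher and 2 lower (list adjusted p = 0.157). SAUR genes (1 of 15 higher, 10 adjusted over the list alone, adjusted p = 1.23e-13), PIF and shade-type regulators (1 of 15, 5 adjusted over the list alone, adjusted p = 1.01e-05) and flowering genes (1 of 15, 3 higher and 1 lower adjusted over the list alone, adjusted p = 0.0449) were higher as lists. With an estimated correlation their adjusted p were 0.0542, 0.0783 and 0.38. In fry they were 0.00652, 0.0209 and 0.177.

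Cold-responsive genes were lower in 2 of 16 at 29 °C, COR27 (log2 fold change -0.66, SE 0.091, adjusted p = 0.00457) and RD29A (-0.90, SE 0.17, adjusted p = 0.0478). Adjusted over the list alone 4 were lower (adjusted p = 1.01e-05, but adjusted p = 0.151 with an estimated correlation). The fry adjusted p of this list was 0.111. Flavonoid (0 of 18 called, adjusted p = 2e-05), jasmonate (0 of 12, adjusted p = 0.000311) and cell division genes (0 of 12, adjusted p = 0.00634) were lower as lists. None was called adjusted over the list alone either, and the lists had adjusted p = 0.38, adjusted p = 0.0783 and adjusted p = 0.436 with an estimated correlation. Their fry adjusted p were 0.236, 0.0209 and 0.19. The other 13 lists had adjusted p from 0.0539 to 0.917. None of their members but 1 cell wall gene, which was lower, was called. Adjusted over the list alone 3 auxin response, 3 cell wall and 2 sugar-starvation genes were higher and 1 of each was lower, as was 1 auxin biosynthesis gene. The named falls were ERD5 (AT3G30775), a proline dehydrogenase gene, by a log2 change of -0.74, SIP2 (AT3G57520) by one of -0.72 and POP2 (AT3G22200) by one of -0.44. SAUR62 was higher by 1.03, CDF3 by 1.05, and the expansin gene EXPA10 (AT1G26770) was lower by a log2 change of -0.47. Without replicate 2 of WT or replicate 1 of the libraries labelled rve5-2 the calls of RD29A, ERD5, SIP2, POP2, SAUR62 and EXPA10 ended, at adjusted p of up to 0.243, 0.137, 0.135, 0.219, 0.0849 and 0.165. Without replicate 2 of the latter all but ERD5 ended, without its replicate 3 all but SAUR62, and without replicate 3 of WT RD29A and ERD5. The count of 102 was 558 without replicate 1 of WT, the library with the lowest root markers, 65 without replicate 2 of WT, and 63 and 52 without replicates 1 and 2 of the libraries labelled rve5-2. Without replicate 1 of WT 3 SAUR genes, 6 PIF and shade-type regulators and 17 light-harvesting genes were higher and 7 flavonoid genes lower, and the flavonoid list then had an adjusted p of 0.0318 with an estimated correlation.

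**Figure D4:**
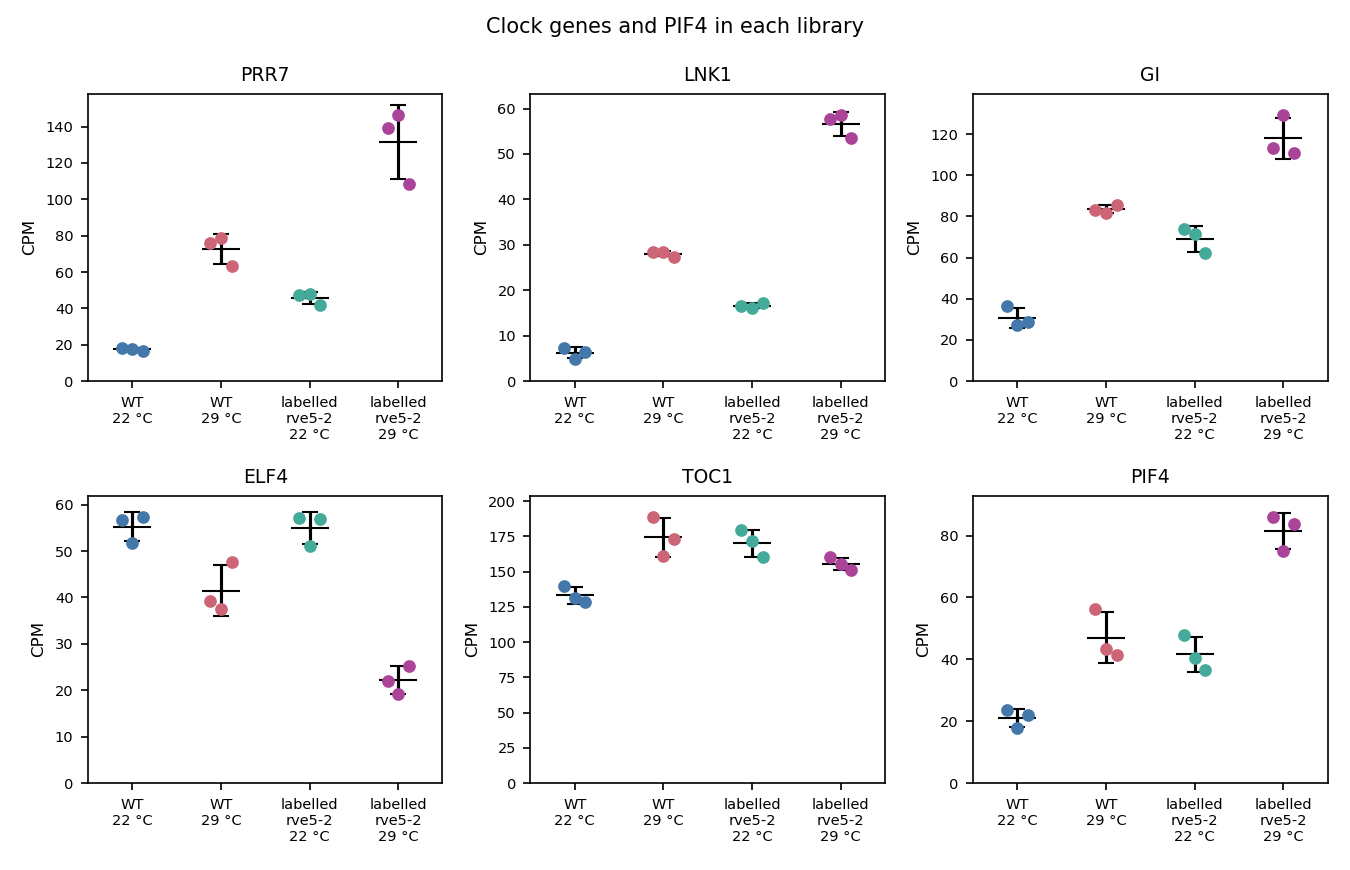
CPM of the clock genes PRR7, LNK1, GI, ELF4 and TOC1 and of PIF4 in each of the 12 libraries, with the mean and SD of each group of 3, on linear axes from 0. PRR7, LNK1 and PIF4 are highest in the libraries labelled rve5-2 at 29 °C, where ELF4 is lowest (22.2 CPM).

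The interaction asks whether the libraries labelled rve5-2 responded to warmth differently from WT. As a list, the evening clock genes had a lower warm response in the libraries labelled rve5-2 than in WT, though not every member did: ZTL (AT5G57360, interaction 0.02) and LKP2 (AT2G18915, 0.0074), named after their values were seen, had almost no difference. The list was lower in the interaction (median log2 difference -0.44, camera adjusted p = 2.82e-17, and adjusted p = 0.00152 with an estimated correlation), and 8 of its 13 members were lower adjusted over the list alone. No single gene passed over all 21870 genes in edgeR, where 1070 had an unadjusted p under 0.05, against 43 genes called in DESeq2 and 3 in limma with quantile normalization. ELF4 had an interaction of -0.90 (SE 0.16, adjusted p = 0.398), TOC1 of -0.52 (SE 0.10, adjusted p = 0.398), FKF1 (AT1G68050) of -0.63 (SE 0.14, adjusted p = 0.586) and GI of -0.66 (SE 0.15, adjusted p = 0.586). Morning clock genes as a list did not pass (adjusted p = 0.607). PIF4 had an interaction of -0.18 (SE 0.19), YUC8 of 1.14 (SE 0.50), CCA1 of 0.69 (SE 0.74), LHY of 0.16 (SE 0.76) and RVE5 of 0.38 (SE 0.13), each with an adjusted p of at least 0.981. Cold-responsive genes were lower as a list (median -0.51, adjusted p = 0.000218, but adjusted p = 0.779 with an estimated correlation). SAUR genes were higher (median 0.43, adjusted p = 0.00301, but adjusted p = 0.846 with an estimated correlation). Light-harvesting and Rubisco small-subunit genes were also higher (median 0.17, adjusted p = 0.0001, but adjusted p = 0.846 with an estimated correlation), and this direction turned with quantile normalization (adjusted p = 0.515). Adjusted over the list alone 2 cold-responsive genes were lower, 1 light-harvesting gene was higher and no SAUR gene was called, and of the lists that did not pass 1 cell wall gene was higher and 1 lower. The other 19 lists had adjusted p from 0.29 to 0.953, and 7 lists passed without replicate 1 of WT at 29 °C. The sign of the median and the direction of the test differed for cell wall genes in WT and flowering genes in the other warm comparison. It also differed for cold-responsive, abscisic acid and seed storage genes at 22 °C, abscisic acid genes at 29 °C, and both auxin lists and seed storage genes in the interaction. None of these lists passed.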

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

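All tests of technical explanations in this part were chosen only after the results were seen, as were the fits with the root score and the list tests without replicate 1 of WT at 29 °C. Differences between 2 groups in their response drew attention here. No test for single libraries far from the rest was applied to groups of 3. By pairs of replicates, replicate 1 of WT at 29 °C stood apart: its 2 pairs had a chi-square per degree of freedom of 30.9 and 32, against 6.92 to 12.1 for the other pairs.

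The evening clock genes answered warmth differently in the libraries labelled rve5-2, where RVE5 is high, than in WT (camera adjusted p = 2.82e-17 for the interaction, and adjusted p = 0.00152 with an estimated correlation). Under the alternatives run on this list one at a time the adjusted p lay between 1.01e-19 and 0.00152. Without replicate 1 of WT at 29 °C, the library with the lowest root markers, the list still passed (adjusted p = 0.015 with an estimated correlation), which argues against that library alone as the cause. The list was not tested without any other library, so dependence on any of those was not checked. With the root score in the fit it passed too (adjusted p = 0.00334 with an estimated correlation), which argues against root share as the whole cause. A shift in the phase of the clock between genotypes could give the same values at a single time of day and stays open, as does an effect of RVE5 itself.

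3 other lists differed between genotypes in their warm response with the preset correlation and not with an estimated one. In fry none of the 3 passed either (adjusted p = 0.789 for each). SAUR genes rose more in the libraries labelled rve5-2 (adjusted p = 0.00301, but adjusted p = 0.846 with an estimated correlation). Cold-responsive genes fell more there (adjusted p = 0.000218, but adjusted p = 0.779 with an estimated correlation). Light-harvesting and Rubisco small-subunit genes rose more there (adjusted p = 1e-04, but adjusted p = 0.846 with an estimated correlation), a direction that turned with quantile normalization.

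The naming rule gave 188 genes over all comparisons. Of these, 5 had groups that did not overlap in 2 matching comparisons but differed in opposite directions. Chance gives 1% only for genes chosen without regard to their values. The naming rule chose genes by non-overlap and by small adjusted p, also in the interaction, so the 5 cannot be set against that 1%. The matching comparisons were the warm responses of the 2 genotypes, or the genotype differences at the 2 temperatures. The directions below are of group means, and most were not called in the single comparisons. The clock gene TOC1 (AT5G61380; 133, 174, 170 and 155 CPM in WT at 22 °C, WT at 29 °C and the libraries labelled rve5-2 at 22 °C and 29 °C; interaction log2 -0.518, adjusted p = 0.398) had a higher mean with warmth in WT (called) and a lower one in the libraries labelled rve5-2 (not called). The brassinosteroid gene DET2 (AT2G38050; 10.4, 12.4, 14.1 and 11.3 CPM; interaction log2 -0.57, adjusted p = 0.954) did likewise, called in neither. The heat shock factor gene HSFA2 (AT2G26150; 2.38, 10.8, 2.96 and 8.27 CPM; interaction log2 -0.71, adjusted p = 0.84) had a higher mean in the libraries labelled rve5-2 at 22 °C and a lower one at 29 °C, and neither difference was called. The means moved the same way for POP2 (AT3G22200; 163, 146, 185 and 108 CPM; interaction log2 -0.625, adjusted p = 0.398) and COR28 (AT4G33980; 14.1, 18.5, 16.7 and 12.7 CPM; interaction log2 -0.789, adjusted p = 0.747), where only the difference of POP2 at 29 °C was called (adjusted p = 0.0418). None of the 5 interactions passed over all genes in edgeR, where 1070 genes had an unadjusted p under 0.05, against 43 called in DESeq2.

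Of the 14 root markers 7 were called lower at 29 °C in each genotype, and the list passed with the preset correlation but not with an estimated one (adjusted p = 0.225 in WT and 0.241 in the libraries labelled rve5-2). In fry it passed in both (adjusted p = 0.0102 and 0.00697). Without replicate 1 of WT at 29 °C 8 were called lower in WT, which argues against that library alone as the cause there. A smaller share of root with all its zones lost alike would lower tip markers and the other root markers alike. In the libraries labelled rve5-2 the medians were log2 -0.33 for 3 tip markers and -2.94 for 11 others (exact permutation p = 0.0165 over markers, which vary together and are not independent). Within each library, the mean log2(CPM + 0.1) of the tip markers minus that of the others was -1.05 ± 0.08 at 22 °C and 1.15 ± 0.54 at 29 °C (SD, n = 3 each, without overlap), which argues against an even loss there. A loss of older, hair-bearing root that spares the tip, and a change within the root, stay open. In WT the medians were -1.19 and -2.66 (exact permutation p = 0.209). The same difference within each WT library was 0.0262 ± 0.737 at 22 °C and 0.947 ± 0.129 at 29 °C (SD, n = 3 each, with overlap). An even loss and the other explanations therefore cannot be told apart in WT.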

How the results depend on the processing

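Chosen only after the data were seen were limma on log2(FPKM + 1), counts divided by 4, the root score as a covariate and the list tests without replicate 1 of WT at 29 °C. RVE5 stayed higher in the libraries labelled rve5-2 under every alternative run, between 6.04 and 6.13 at 22 °C and between 6.38 and 6.54 at 29 °C with each library left out. Its rise with warmth there weakened to 0.195 with quantile normalization and to 0.152 with the root score. Called genes numbered 3387, 5696, 42, 102 and 0 for the warm response of WT, that of the libraries labelled rve5-2, the genotype difference at 22 °C and at 29 °C, and the interaction. A 2-fold minimum left 699, 1270, 18 and 38 by construction. The root score gave 175, 511, 70 and 195. With only the compared groups in the fit, which has fewer libraries, there were 1687 for WT and 75 and 38 for the genotype differences. Array weights gave 70 and 778 (223 higher and 555 lower, against 70 and 32 in edgeR) and DESeq2 143 and 345 for the genotype differences, and the interaction had 43 in DESeq2 and 3 with quantile normalization. The cause of these was not tested. With each library left out the counts were 1747 to 3621, 3590 to 5239, 25 to 48, 52 to 558 (the highest without replicate 1 of WT at 29 °C) and 0 to 1. Each group that lost a library was assumed to vary like the others. With the replicate number as a block they were 3829, 5954, 42, 123 and 0. The numbers were not taken as pairs, since they are not stated to pair libraries. In deviations from group means, 3 of 18 pairs of libraries with the same number correlated above 0.1 (r from -0.0249 to 0.21). With different numbers it was 1 of 36 (r from -0.218 to 0.102). Across genotypes at 29 °C, r was 0.188, 0.0124 and 0.21 for the same number and -0.218 to 0.076 for different numbers. A shared structure of the replicates there is therefore not excluded.

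The correlation of the 2 warm responses, 0.546, was 0.848 and 0.832 with pseudocounts of 0.5 and 0.1, 0.854 on log2(FPKM + 1), 0.852 with quantile normalization, 0.847 at a mean FPKM of at least 5, 0.733 with counts divided by 4, 0.28 without a filter, and 0.406 to 0.489 with each library left out. That of the 2 genotype differences, 0.0951, was 0.336, 0.303, 0.358, 0.358, 0.406, 0.186 and 0.0262 in the same order, and 0.0432 to 0.078 with each library left out. Both were higher where fewer genes with low counts were tested. Lists that passed numbered 11, 9, 10, 9 and 4 in the order of the comparisons above, and 3, 2, 4, 2 and 1 with an estimated correlation. With the root score 5 passed for the warm response of the libraries labelled rve5-2, and without replicate 1 of WT at 29 °C 12 passed for that of WT, 10 for the genotype difference at 29 °C and 7 for the interaction. The light-harvesting list in the interaction turned its direction with quantile normalization (adjusted p = 0.515), and the cause was not tested. Over 181 results of named genes 2757 alternatives kept the direction and the side of the threshold, 303 were weaker, 5 stronger and 0 reversed. Over 115 list results these were 918, 54, 16 and 1. In the simulated data 43 to 72% of 2-fold changes, all in genes well above the count filter, were recovered at this depth and group size. The part that depth alone plays was not measured.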

Other observations

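The splits of the libraries were planned, and the other tests here were chosen only after the results were seen.

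By gene ontology terms, the genes called higher with warmth in WT were enriched for response to heat (62 of 204, 16.3 expected, adjusted p = 5.74e-18, the smallest of the terms) and chlorophyll binding (11 of 25, 2 expected, adjusted p = 9.76e-05). Those called lower were enriched for trichoblast differentiation (33 of 44, 3.55 expected, adjusted p = 1.9e-24), glycolytic process (61 of 187, 15.1 expected) and response to nitrate (56 of 190, 15.3 expected). In the libraries labelled rve5-2 the genes called higher with warmth were enriched for thylakoid (88 of 185, adjusted p = 4.24e-28). Those called lower were enriched for response to nitrate (108 of 190, 26.7 expected, adjusted p = 1.44e-40) and iron ion transport (54 of 111, 15.6 expected). Trichoblasts are root hair cells, and nitrate and iron uptake take place in roots. The root score fell with warmth from 2.60 to 0.36 in WT and from 2.70 to 0.26 in the libraries labelled rve5-2, so these terms are not separate from the fall of the root markers. Genes higher in these libraries than in WT were enriched for chlorophyll binding at 22 °C (9 of 25, 0.0401 expected, adjusted p = 3.76e-17) and at 29 °C (13 of 25, 0.0882 expected, adjusted p = 1.89e-23). At 22 °C they were also enriched for circadian rhythm (5 of 127, 0.204 expected, adjusted p = 0.000152).

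RVE5 was 67.7-fold higher at 22 °C in the libraries labelled rve5-2, where a loss of its transcript would give lower counts. Counts per gene from libraries that do not mark the strand cannot tell a whole transcript from part of one, or sense from antisense. An interrupted gene is therefore not excluded. Of the 50-base stretches of RVE5, 0% occur elsewhere in the reference genome, which argues against reads from related genes. The other REVEILLE genes, CCA1 and LHY together reached 13.5% of the gain at 22 °C and 12.3% at 29 °C. That sum cannot decide, since reads wrongly counted at RVE5 would be missing from it. An exchange of all genotype names stays open, because it would only invert the 67.7-fold difference. Transcription from DNA inserted at the locus also stays open: 0 of 10 neighbours of RVE5 were called higher in edgeR and 1 was lower, but a promoter facing only RVE5 would leave them as they are. A line made to express more RVE5 may give the same values and was not tested.

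A hypothesis from these data is that genes higher in the libraries labelled rve5-2 tend to be genes that rise with warmth. It came from these same calls, so their overlap describes it and is not an independent test. Of the 70 genes higher in them at 29 °C, 44 also rose with warmth in WT (5.66 expected) and 2 fell. Of the 30 higher at 22 °C, 23 also rose with warmth in the libraries labelled rve5-2 (3.91 expected) and 1 fell. Each pair of comparisons shares a group whose chance errors push the comparisons apart, so this overlap is not due to the sharing. Among lower genes the overlaps were 11 of 32 (2.37 expected) and 1 of 12 (1.56 expected), and 6 of each rose with warmth. The genes are not independent of each other, so a shared response of antenna and clock genes could make up much of it.

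A stretch of chromosome 1 (21769762 to 21843745) held 11 tested genes, of which 7 were called lower in the libraries labelled rve5-2 at both temperatures. The 7 had log2 changes of -0.804 to -0.595 at 22 °C and -0.914 to -0.532 at 29 °C. Of the genes around it, 0 of 20 were called at either temperature in edgeR, with median log2 changes of 0.03 and -0.0054. Between 99.1 and 100% of the 50-base stretches of the 7 genes also occur elsewhere in the reference genome, so they are not 7 separate measurements. Chosen after their values were seen, the flowering regulator gene COL5 (AT5G57660) stood at 12.3, 26.1, 26 and 57.4 CPM and the thionin gene THI2.2 (AT5G36910) at 8.4, 12.8, 23.4 and 35.6 CPM in WT at 22 °C, WT at 29 °C and the libraries labelled rve5-2 at 22 °C and 29 °C.

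The 6 libraries of a comparison allow 10 splits into 3 and 3, too few for a share under 0.05. The real splits called 3387, 5696 and 42 genes for the warm responses of WT and of the libraries labelled rve5-2 and the genotype difference at 22 °C, and the highest other split called 1 in each, so 1 of 10 splits gave as many. For the genotype difference at 29 °C the real split called 102, and 2 of 10 splits gave as many. The other called 276 and set replicate 1 of WT and replicates 1 and 2 of the libraries labelled rve5-2, the 3 libraries with the lowest root scores at 29 °C, against the rest. This points to a structure of the samples that follows the root markers. For the interaction the real count in edgeR was 0 (1070 genes at an unadjusted p under 0.05, 43 called in DESeq2), which all 100 of 100 labellings drawn from 200 had to reach, so this comparison says nothing about chance. The highest labelling, 150, came from exchanging the genotype names at 29 °C alone. That exchange turns the interaction into the sum of the 2 genotype differences, with its sign turned. The 150 are therefore genes that differ between genotypes over both temperatures, and do not bear on whether names were exchanged.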
